A study of Mus musculus with 18 samples.

How the data were processed

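Hippocampus of C57BL/6 mice, WT or with a conditional knockout of Arid1a, was profiled by polyA RNA-seq (10 libraries) and by ChIP-seq for 3 histone marks and input (8 libraries). Groups were taken from the sample titles: 2 WT and 2 cKO RNA libraries at P21, 3 WT and 3 cKO RNA libraries at E16.5, and 1 library per genotype for each mark and for input at 3 weeks. The series design states biological replicates for RNA and none for ChIP-seq. All samples were sequenced on BGISEQ-500 per the series design.

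For RNA the authors deposited 1 table of estimated counts per gene for each age, made with Salmon 1.0.0 against GRCm38 per the submitters' processing notes. How transcript estimates were summed per gene is not given in the sources used here, nor whether strand was used. Between 20.8% and 22.5% of the values in a library, zeros included, were not whole, and library totals were 20089631 to 20332148 at P21 and 17662335 to 19760764 at E16.5. The authors also deposited a table per age with log2 fold changes and their standard errors, a p-value and adjusted p-value, and a score for the mean level (baseMean), from DESeq2 1.26.0 per the submitters' processing notes. In these tables adjusted p-values of 1 stand where p-values are missing.

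For ChIP-seq the authors deposited 1 peak list per mark and genotype, called on single libraries with the input of the same genotype as control, per the file headers. Alignment used Bowtie2 2.3.5.1 and GRCm38 per the submitters' processing notes. The notes name MACS2 2.2.5, while the file headers give MACS version 2.2.7.1, narrow peaks and a q-value limit of 0.01. Per the file headers each peak has a pileup signal at the summit, a fold enrichment ratio over the local input expectation, and p-values and q-values as −log10. The larger of the treated and input libraries was scaled down to the smaller, and no duplicate tags remained, per the file headers. Fold enrichments are the authors' and were used to describe peaks and to pick the highest ones named, and top-ranked peaks in the overlap alternatives were ranked by q-value. Narrow calling can split a broad H3K27me3 domain into several peaks, so covered length is given beside the number of peaks. The 2 input libraries entered through these peak lists, and no file of their own was used here.

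Estimated counts were rounded to whole numbers. Gene symbols came from the authors' deposited tables, and gene coordinates from a RefSeq gene table of assembly GRCm38.p6 matched on the symbol or, where that failed, on the Entrez identifier in the authors' tables, which gave coordinates for 91.6% of tested genes at each age. That table has no strand or transcript starts, so peaks were assigned to a gene when they lay within 1 kb of either of its ends, instead of the promoter windows planned beforehand.

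Differential expression was tested with edgeR 4.0.16 (R 4.3.3) for each age alone, after filterByExpr and TMM scaling, by the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are approximate, derived from the F statistic. The difference between ages was the contrast of the cKO effects in 1 fit of the 10 libraries. The 29 gene lists had been fixed before the data were examined, as had the tests. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera also uses the residual degrees of freedom of the fit, which are few here. Overlaps and peak associations were tested with Fisher's exact test, two-sided (scipy 1.17.1 and R). Peaks were compared with bedtools 2.31.1 at an overlap of at least 1 bp, with Wilson 95% intervals that cover counting error only.

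Genes were named by a rule fixed before the data were examined: Arid1a, the 8 highest and 8 lowest changes among genes past the threshold with a mean of at least 5 CPM in the higher group, groups that do not overlap and a symbol that is not a model name, up to 3 members per list with the lowest adjusted p or, where none passed, the closest 1, and the 5 highest and 5 lowest differences between ages. For the differences, groups that do not overlap were required at either age. Members of a list beyond the rule, named where 5 or fewer passed or beside the list as a contrast, were chosen after their values were seen, and so were the strongest peaks and the list peak counts given as examples. Some members of lists and some of the strongest peaks are not reported here. A gene with no counts in 1 group was set against a floor of 3 counts per library.

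The pipeline was tested on simulated counts with 200 changed genes drawn from the real means, dispersions and library sizes. Of 2-fold changes 58% were recovered at P21, 53% at E16.5 and 21% for the difference between ages, and of 4-fold changes 85%, 72% and 54%. False calls numbered 27 of 170, 10 of 135 and 4 of 79. The simulated share of false calls lies above the threshold of 0.05 in each of these comparisons. Replicates of a group differed by more than counting noise in each pair (chi-square per degree of freedom 8.43 to 44.9), so none was counted as a repeat deposit.

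Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom, no filter, a filter at 1 CPM, an adjusted p under 0.01, at least 2-fold changes, each library left out, the replicate number as a block, 1 fit of all libraries, stricter peaks, larger overlaps, equal numbers of top-ranked peaks and a window of 2.5 kb. Added after seeing the data were covariates for sex and for tissue markers at E16.5, edgeR without robust fitting, the likelihood ratio test, the whole gene span, a test of peaks gained among genes without a WT end peak, and the overlap between ages without Arid1a.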

Results

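Hippocampi of wild-type (WT) mice and of mice with a conditional knockout (cKO) of Arid1a were profiled by RNA sequencing and by chromatin immunoprecipitation sequencing (ChIP-seq). Arid1a encodes a DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complex. The 10 RNA libraries comprised 2 WT and 2 cKO libraries at 3 weeks after birth (P21) and 3 WT and 3 cKO libraries at embryonic day 16.5 (E16.5). The 8 ChIP-seq libraries were made at 3 weeks with 1 library per genotype for H3K4me3, a mark of active promoters, H3K27ac, a mark of active promoters and enhancers, H3K27me3, the mark of Polycomb repression, and input. RNA libraries held 20089631 to 20332148 estimated counts at P21 and 17662335 to 19760764 at E16.5. Expression is given in CPM, counts scaled to the TMM-adjusted library size, and changes as cKO over WT on the log2 scale with an approximate standard error (SE). The RNA replicates were biological per the series design, which states none for ChIP-seq. The labels do not say in which cells Arid1a was deleted.

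Arid1a (chromosome 4, 133679008 to 133756769, GRCm38) was lower in each cKO library than in each WT library of its age. At P21 it had 4291 and 4089 counts in WT and 2281 and 1778 in cKO, and at E16.5 it had 4983, 5489 and 5560 counts in WT and 3210, 3100 and 3527 in cKO. Its level fell from 210 ± 6.98 CPM (SD, n = 2) to 99.6 ± 14.7 CPM (SD, n = 2) at P21, a log2 change of -1.08 (SE 0.13, edgeR adjusted p = 0.00507). At E16.5 it fell from 276 ± 12.5 CPM (SD, n = 3) to 177 ± 2.5 CPM (SD, n = 3), a log2 change of -0.64 (SE 0.06, edgeR adjusted p = 0.032). Total Arid1a counts include any transcript that lacks the deleted part. The sex-linked check genes separated the libraries by sex and not by genotype. Xist had 37 and 21 counts in WT and cKO replicate 1 at P21 against 4914 and 3572 in replicate 2. At E16.5 it had 7 and 10 counts in WT and cKO replicate 3, and 6491 to 9159 in the other libraries. Of these 6 check genes, 6 were tested at P21 and 1 at E16.5, and 0 passed edgeR at either age, over all genes or adjusted over the list alone, as 0 did at an unadjusted p under 0.05 or by DESeq2.

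At P21, 489 genes were higher and 680 lower in cKO among 17407 genes tested, and 267 and 277 of them changed at least 2-fold. Among the genes that rose most were Matn1, a cartilage matrix protein, from 0.301 ± 0.000255 to 10.8 ± 2.21 CPM (SD, n = 2 per genotype), Dlk1, an imprinted Notch-ligand-like protein, from 5.09 ± 0.669 to 44.1 ± 7.53 CPM, and Twist1, a mesodermal transcription factor, from 1.83 ± 0.317 to 12.3 ± 1.5 CPM. Etnppl, an astrocyte-enriched phospholyase, rose by 3.13 on the log2 scale (SE 0.30), Ctla2a by 2.55 (SE 0.23) and Fbln5, an elastic-fibre protein, by 2.49 (SE 0.33). Genes that fell most were Egr2, an activity-induced transcription factor (-3.77, SE 0.49), Rlbp1, a retinaldehyde-binding protein of glia (-3.51, SE 0.23), the microglial genes Fcrls (-3.04, SE 0.46) and Itgam (-2.71, SE 0.20), Capn3 (-2.90, SE 0.25), Lcat, the enzyme that esterifies cholesterol in lipoproteins (-2.90, SE 0.19), Tnfrsf25 (-2.59, SE 0.16) and Gdpd2 (-2.58, SE 0.25). The edgeR adjusted p of these genes lay between 0.00049 and 0.0168. Matn1 lies on chromosome 4 within 10 Mb of Arid1a, in a window where other-strain DNA remains undecided (see the last paragraph). Ugt1a6a rose from 0.802 ± 0.213 to 13.5 ± 3.96 CPM. Ugt1a6b had no counts in WT and 7.66 ± 1.36 CPM in cKO, at least 51-fold above a floor of 3 counts per library. These glucuronosyltransferase genes overlap on chromosome 1 and share exons, so the split of reads between them is uncertain.

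The counts of changed genes at P21 rested on few libraries and on the model fitted. Without WT replicate 1 edgeR called 249 genes higher and 394 lower, without WT replicate 2 it called 138 and 293, without cKO replicate 1 it called 1244 and 1627, and a fit of all 10 libraries called 155 and 350. The fit of all 10 libraries drops no P21 library but shares its estimate of replicate spread with E16.5. The common coefficient of variation was 0.146 at P21 alone, 0.25 at E16.5 alone and 0.231 in the joint fit. Of the calls of the P21 fit, 41.8% were higher in cKO, against 52.3% with upper-quartile scaling, while the median change of all genes stayed within 0.06 under each scaling. Groups did not overlap for 56.1% of tested genes, where chance gives 33.3%. The authors' deposited table called 485 genes higher and 841 lower at P21, and shared 377 and 626 with edgeR.

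The glial lists of this paragraph stand beside a difference in striatal markers between the same libraries (mean log2 CPM 2.06 and 2.26 in WT, 3.09 and 3.7 in cKO). The oligodendrocyte lineage list shifted down at P21 by camera (adjusted p = 5.89e-25; adjusted p = 0.214 with an estimated correlation). Its estimated correlation, -0.048, lay below the preset 0.01. The unadjusted camera p still went from 2.1e-26 to 0.00765, since the second test has few degrees of freedom. Of 15 genes of the oligodendrocyte lineage, 0 rose and 11 fell (13 adjusted over the list alone). The myelin proteins Mog (107.5 ± 7.50 to 30.1 ± 1.54 CPM, log2 -1.84, SE 0.11), Opalin (-1.69, SE 0.15) and Cnp (-1.14, SE 0.10) were among them (SD, n = 2 per genotype). The progenitor markers Pdgfra (0.16, SE 0.10) and Cspg4 (0.04, SE 0.15), named after their values were seen, did not pass. Of 12 microglial genes 5 fell and 0 rose (6 fell and 1 rose adjusted over the list alone). P2ry12 (22.6 ± 2.78 to 4.66 ± 0.913 CPM, -2.27, SE 0.19), Tmem119 (-1.98, SE 0.27) and Cx3cr1 (-1.15, SE 0.17), markers of resting microglia, fell with the lowest adjusted p of this list, and Csf1r fell by 0.66. The complement genes C1qa (0.10, SE 0.16), C1qb (0.02, SE 0.16) and C1qc (0.01, SE 0.17), again named after their values were seen, did not pass. Camera gave adjusted p = 3.64e-05 for microglia (adjusted p = 0.537 with an estimated correlation). Among 11 astrocyte genes 4 fell and 1 rose (6 and 1 adjusted over the list alone), with S100b (-2.42, SE 0.15), Slc7a10 (-1.29, SE 0.13), Ppp1r3c (-0.67) and Aqp4 (-0.50) lower and the gap-junction gene Gjb6 higher (0.73, SE 0.13). The camera test of this list was down (adjusted p = 0.000261; adjusted p = 0.509 with an estimated correlation). Of 11 tested genes of reactive glia and inflammation, Osmr rose (1.15, SE 0.25) and C4b fell (-1.66, SE 0.29), with 1 rising and 2 falling adjusted over the list alone, and the list did not pass (camera adjusted p = 0.278).

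**Figure D1:**
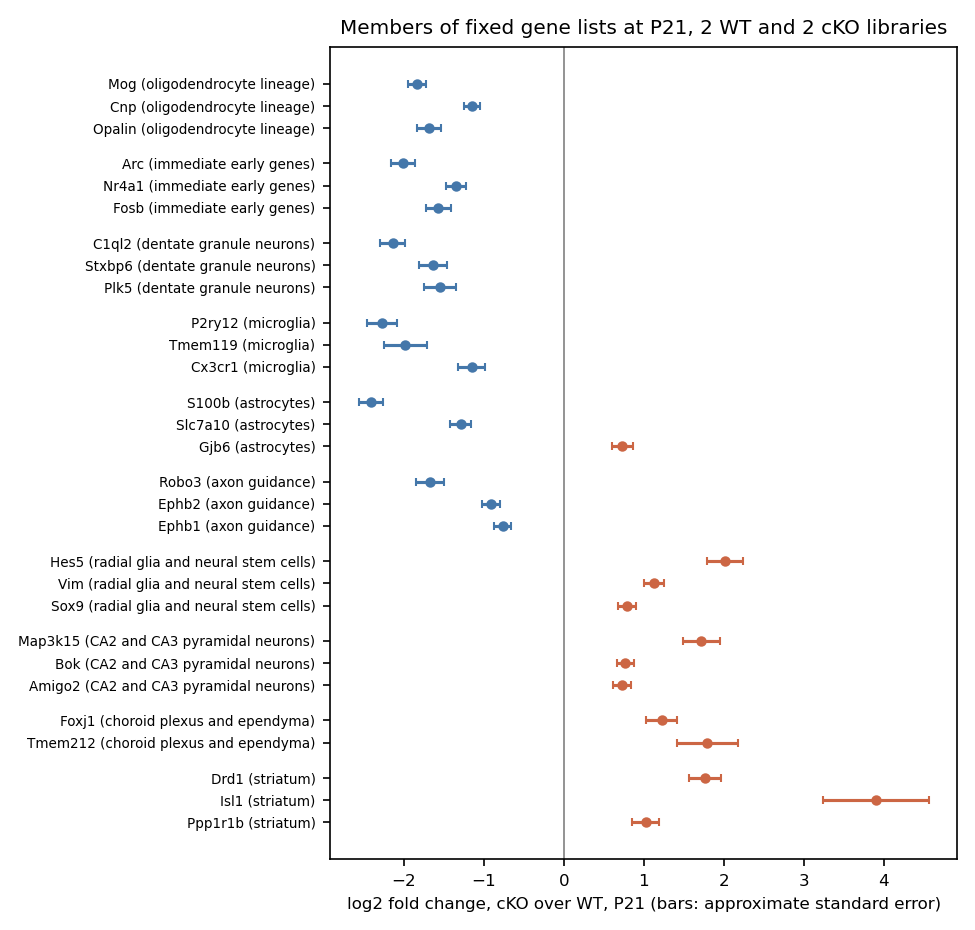
Log2 fold change, cKO over WT, of named genes of the 10 lists that passed camera at P21, with bars for the approximate standard error (2 WT and 2 cKO libraries). Oligodendrocyte, immediate early, dentate, microglial and axon guidance genes lie below 0, from P2ry12 at -2.27 to Ephb1 at -0.76, and striatal genes above 0, where Isl1 rests on a WT mean of 0.0501 CPM.

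Neuronal genes went both ways at P21. These changes stand beside a difference in striatal markers between the same libraries, with a mean log2 CPM of 2.06 and 2.26 in WT and 3.09 and 3.70 in cKO. Of 13 immediate early genes, which neurons transcribe within minutes of activity, 8 fell and 1 rose (10 and 1 adjusted over the list alone). Arc fell from 277 ± 17.9 to 68.7 ± 13.2 CPM (SD, n = 2 per genotype; log2 -2.01, SE 0.15), Fosb by 1.57 (SE 0.15) and Nr4a1 by 1.35 (SE 0.12), while Dusp1, a phosphatase that counters MAP kinases, rose by 0.61 (SE 0.14). Camera gave adjusted p = 2.26e-19 for this list (adjusted p = 0.231 with an estimated correlation). Of 13 dentate granule neuron genes 7 fell and 0 rose (8 adjusted over the list alone), among them C1ql2 (25.8 ± 2.64 to 5.85 ± 0.094 CPM, -2.14, SE 0.15), Stxbp6 (-1.64, SE 0.18) and Plk5 (-1.55, SE 0.20). Prox1, the transcription factor that sets granule cell identity, fell by 1.86 (SE 0.28), whereas Calb1 had 0.13 (SE 0.19). The list passed camera (adjusted p = 1.95e-12; adjusted p = 0.509 with an estimated correlation). Among 11 genes of CA2 and CA3 pyramidal neurons Map3k15 (1.72, SE 0.24), Bok (0.77, SE 0.11) and Amigo2 (0.73, SE 0.11) rose and Pcp4 fell (-0.42), with 5 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.579 with an estimated correlation). Wfs1 rose (1.12, SE 0.16) as 1 of 9 CA1 genes, also adjusted over the list alone, and the CA1 list, with a median of -0.07 and a mean of 0.10, did not pass (camera adjusted p = 0.42). Of 29 axon guidance genes 5 fell and 0 rose (6 adjusted over the list alone), namely Robo3 (-1.68, SE 0.18), Ephb2 (-0.91, SE 0.11), Ephb1 (-0.76, SE 0.11), Plxna4 (-0.68) and Efnb3 (-0.47), and camera gave adjusted p = 0.00207 (adjusted p = 0.579 with an estimated correlation). Homer1 (-0.59, SE 0.13) and Nrgn (-0.51, SE 0.11) fell among 23 genes of the glutamatergic synapse, the same number as adjusted over the list alone (camera adjusted p = 0.18), and 0 of 17 genes of GABAergic interneurons passed edgeR, over all genes or adjusted over the list alone (5 higher and 1 lower at an unadjusted p under 0.05, and 1 higher by DESeq2; camera adjusted p = 0.225). Npy was closest (0.58, SE 0.15, edgeR adjusted p = 0.0569).

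Among 15 genes of radial glia and neural stem cells, Hes5, a Notch target (2.03 ± 0.175 to 8.24 ± 0.404 CPM, SD, n = 2 per genotype; log2 2.02, SE 0.22), Vim (1.13, SE 0.13), Sox9 (0.79, SE 0.12) and Sox2 (0.50) rose, and Emx2 (-1.35) and Fabp7 (-1.18) fell. Adjusted over the list alone 7 rose and 2 fell, and camera gave adjusted p = 0.048 (adjusted p = 0.579 with an estimated correlation). The mean log2 CPM of this list was 4.6 and 4.54 in WT and 4.84 and 4.66 in cKO replicates 1 and 2. Replicate 1 of cKO also had the highest level of choroid plexus and ependymal genes (4.3, against 3.1 to 3.32 in the other P21 libraries). Of 13 tested genes of intermediate progenitors and neuroblasts, Sox11 (-0.99, SE 0.13), Nhlh1 (-2.29, SE 0.41) and Igfbpl1 (-1.5, SE 0.34) fell (5 adjusted over the list alone; camera adjusted p = 0.0878). Top2a fell (-1.69, SE 0.34) as 1 of 20 cell division genes (2 adjusted over the list alone; camera adjusted p = 0.486). The cyclin-dependent kinase inhibitor Cdkn1a rose from 13.1 ± 3.38 to 62.8 ± 12.4 CPM (2.26, SE 0.22) and Trp53inp1 by 0.73 (SE 0.13) among 14 p53 target and apoptosis genes. In that list 2 rose and 1 fell adjusted over the list alone, the median was -0.07 and the mean 0.19, and it did not pass (camera adjusted p = 0.303).

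Of the lists for neighbouring and supporting tissues, striatum and choroid plexus and ependyma passed camera at P21. Of 11 striatal genes 3 rose and 0 fell (6 adjusted over the list alone). The dopamine receptor Drd1 rose from 3.83 ± 0.245 to 13.0 ± 1.93 CPM (SD, n = 2 per genotype; log2 1.76, SE 0.20), Ppp1r1b by 1.02 (SE 0.17), and Isl1 from 0.0501 to 0.836 CPM, and camera gave adjusted p = 5.87e-06 (adjusted p = 0.579 with an estimated correlation). Of 13 genes of choroid plexus and ependyma, the ciliary genes Foxj1 (1.22, SE 0.19) and Tmem212 (1.80, SE 0.38) rose, as they did adjusted over the list alone (camera adjusted p = 0.048; adjusted p = 0.644 with an estimated correlation). The mean log2 CPM of this list was 3.32 and 3.10 in WT and 4.30 and 3.19 in cKO replicates 1 and 2. Ttr, the most abundant choroid plexus transcript, had 3429 CPM in cKO replicate 1 and 949.5 CPM in cKO replicate 2 against 1304 and 1077 CPM in WT. Wnt8b rose (2.09, SE 0.48) among 11 tested genes of cortical hem and Cajal-Retzius cells (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.064), and Lhx9 rose (1.02, SE 0.14) among 9 thalamic genes, also adjusted over the list alone (camera adjusted p = 0.216). Pecam1 (0.66, SE 0.12) and Cldn5 (0.86, SE 0.17) rose and Tek fell (-0.89, SE 0.18) among 14 endothelial and mural genes, the same counts as adjusted over the list alone (camera adjusted p = 0.112). Col3a1 fell (-0.89, SE 0.21) among 10 genes of meningeal fibroblasts (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.283).

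Of 27 other BAF subunits at P21, the neuronal subunits Dpf3 (-1.43, SE 0.25) and Actl6b (-0.45, SE 0.10) fell, as adjusted over the list alone (camera adjusted p = 0.303), and of 21 writers and erasers of the profiled marks Hdac1 fell (-0.62, SE 0.14), with 0 adjusted over the list alone (2 higher and 8 lower at an unadjusted p under 0.05, 1 and 1 by DESeq2; camera adjusted p = 0.267). Hapln1 (-0.68, SE 0.13) and Ncan (-0.63, SE 0.13), of perineuronal matrix, fell among 25 genes of extracellular matrix and cell adhesion (3 adjusted over the list alone; camera adjusted p = 0.553), and Ccnd1 (-1.0, SE 0.17) fell among 11 canonical Wnt targets (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.435). Of 5 erythrocyte genes and 13 mitochondrially encoded RNAs 0 passed edgeR, over all genes or adjusted over the list alone (0 and 1 at an unadjusted p under 0.05, 1 and 1 by DESeq2; camera adjusted p = 0.303 and 0.653). Alas2 had a log2 change of 1.42 (SE 0.71) and mt-Nd2 of -0.32 (SE 0.11), and the mitochondrial list had a median of 0.03 and a mean of -0.04. The 39 Hox genes together had 12 to 16 counts per library at P21 and 8 to 27 at E16.5, and none was tested. In total 10 of 28 lists passed camera at P21, and 0 did with an estimated correlation. Few degrees of freedom there leave undecided whether correlation between genes accounts for the shifts. By fry, which asks whether a list's genes move one way, the oligodendrocyte list passed (adjusted p = 0.0323). Without cKO replicate 1 camera called 6 lists.

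At E16.5 edgeR called 2 genes higher and 19 lower in cKO among 16958 tested. The proneural transcription factor Neurog1 rose from 0.345 ± 0.0327 to 9.89 ± 2.06 CPM (SD, n = 3 per genotype; log2 4.82, SE 0.26, edgeR adjusted p = 0.0103), and the pentraxin Ptx3 from 14.1 ± 2.33 to 37.8 ± 4.79 CPM (1.42, SE 0.15, edgeR adjusted p = 0.0472). The neuropeptide gene Grp fell from 16.8 ± 2.70 to 0.711 ± 0.20 CPM (-4.56, SE 0.26, edgeR adjusted p = 0.0103) and the proteoglycan Bcan from 113 ± 8.54 to 11.97 ± 3.28 CPM (-3.24, SE 0.20, edgeR adjusted p = 0.0112). Aox4 (-2.44, SE 0.25), the glycolytic enzyme Aldoc (-2.35, SE 0.22), the matrix genes Fbln2 (-2.32, SE 0.17) and Spp1 (-2.28, SE 0.24), Cdc42ep1 (-1.87, SE 0.19) and Inka2 (-1.85, SE 0.11) also fell, with edgeR adjusted p between 0.0103 and 0.0472. DESeq2 called 352 genes higher and 714 lower on the same counts, as did the authors' deposited table, and its calls included all 21 of the edgeR calls.

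These calls depended on single libraries and on the terms of the model. With the replicate number as a block, which includes sex, edgeR called 0 genes in either direction (719 higher and 1231 lower at an unadjusted p under 0.05), and with sex as a covariate 1 and 3, each among the 21 calls. Without WT replicate 1 or without WT replicate 3 edgeR called 0 genes in either direction, with 997 higher and 1335 lower, and 1281 and 1780, at an unadjusted p under 0.05, against 1548 and 1951 in all libraries. Without WT replicate 2 it called 4 higher and 4 lower, without cKO replicate 1 it called 1 and 8, and without cKO replicate 2 it called 1 and 5. Groups did not overlap for 29.2% of tested genes, where chance gives 10%.

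Meningeal fibroblast genes had the lowest median change of the lists tested at E16.5, and levels of meningeal and choroid plexus genes varied between libraries of 1 genotype. The mean log2 CPM of 10 meningeal fibroblast genes was 6.21, 3.06 and 3.52 in WT replicates 1 to 3 and -0.71, -0.10 and 2.39 in cKO replicates 1 to 3. That of choroid plexus and ependymal genes was 5.64, 5.13 and 0.45 in WT and -1.75, 0.70 and 4.89 in cKO. Ttr had 4566, 3070 and 16.3 CPM in WT and 0.953, 27.1 and 2336 CPM in cKO. The collagen Col3a1 had 111 ± 120 CPM in WT and 7.08 ± 6.90 CPM in cKO (SD, n = 3 per genotype; edgeR adjusted p = 0.167). Of the meningeal genes 0 passed edgeR over all genes and 7 fell adjusted over the list alone (9 lower at an unadjusted p under 0.05, 8 by DESeq2), with a median log2 change of -3.48 (camera adjusted p = 2.59e-06; adjusted p = 0.433 with an estimated correlation). Of 11 choroid plexus and ependymal genes 0 passed edgeR, also adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2 (median -1.41; camera adjusted p = 0.0459; adjusted p = 0.769 with an estimated correlation). Of 14 endothelial and mural genes 0 passed edgeR and 2 fell adjusted over the list alone (9 lower at an unadjusted p under 0.05, 4 by DESeq2; camera adjusted p = 2.96e-06; adjusted p = 0.433 with an estimated correlation), with Acta2 at -3.31 (SE 0.75).

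**Figure D2:**
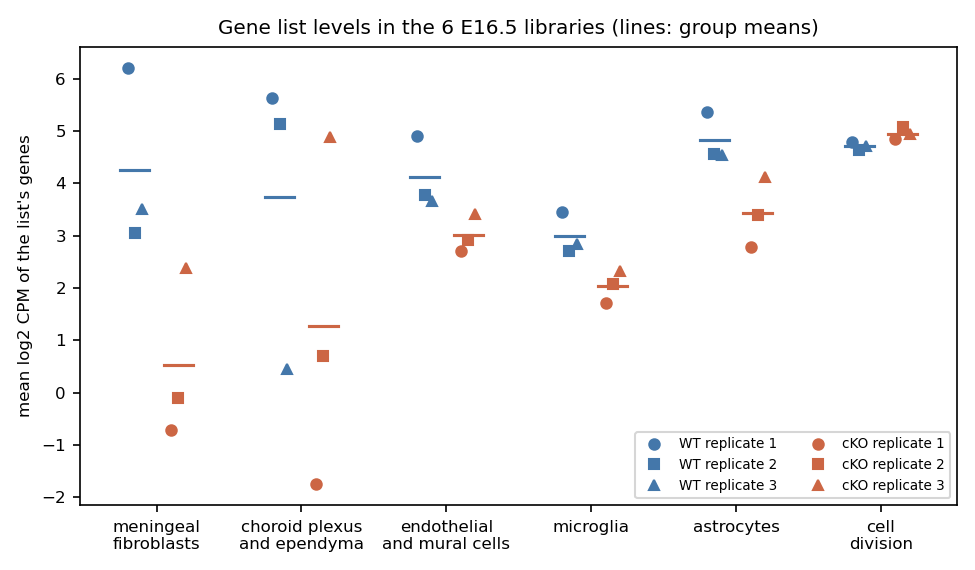
Mean log2 CPM of the genes of 6 lists in each of the 6 E16.5 libraries, with lines for the group means. Choroid plexus and ependymal genes split each genotype (WT 0.45 to 5.64, cKO -1.75 to 4.89), while meningeal genes lay between 3.06 and 6.21 in WT and between -0.71 and 2.39 in cKO.

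Beside each of the following lists stands the difference of -3.74 in mean log2 CPM of meningeal genes between genotypes. Of 24 tested genes of extracellular matrix and cell adhesion Bcan fell and 0 rose (3 fell adjusted over the list alone, 0 were higher at an unadjusted p under 0.05 or by DESeq2; camera adjusted p = 9.83e-10; adjusted p = 0.397 with an estimated correlation). Of 10 astrocyte genes Aldoc fell (3 adjusted over the list alone), and each of the 10 had a negative change, with a median of -1.33 (camera adjusted p = 4.33e-07; adjusted p = 0.397 with an estimated correlation). Of 12 microglial genes 0 passed edgeR over all genes and 9 fell adjusted over the list alone (9 lower at an unadjusted p under 0.05, 7 by DESeq2), with Cx3cr1 at -1.19 (SE 0.25). Camera gave adjusted p = 9.56e-07 for microglia (adjusted p = 0.433 with an estimated correlation).

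The next 7 lists were also lower by camera at E16.5, and 0 of their genes passed edgeR over all genes. In each of them cKO replicate 1 had the lowest mean log2 CPM of the 6 libraries. For canonical Wnt targets it had 2.52, against 3.72 and 3.69 in the other cKO libraries and 4.64, 4.0 and 4.11 in WT, and for thalamus 2.79, against 3.76 and 4.14, and 4.26, 4.16 and 3.99 in WT. Of 8 genes of reactive glia and inflammation, with Osmr at -1.05, 0 passed adjusted over the list alone (3 lower at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.0015; adjusted p = 0.433 with an estimated correlation). Of 13 oligodendrocyte lineage genes, with Cspg4 at -0.62, 0 passed adjusted over the list alone (4 lower at an unadjusted p under 0.05, 2 by DESeq2; camera adjusted p = 0.0015; adjusted p = 0.397 with an estimated correlation). Of 12 dentate granule neuron genes, with Lct at 0.916 CPM in WT and 0.0853 CPM in cKO, 2 fell adjusted over the list alone (2 lower at an unadjusted p under 0.05, 1 by DESeq2; camera adjusted p = 0.0015; adjusted p = 0.433 with an estimated correlation). Of 12 canonical Wnt targets, with Tcf7 at -0.93, 0 passed adjusted over the list alone (4 lower at an unadjusted p under 0.05, 2 by DESeq2; camera adjusted p = 0.00244; adjusted p = 0.46 with an estimated correlation). Of 23 genes of the glutamatergic synapse, with Grin2b at -0.43, 1 fell adjusted over the list alone (1 higher and 6 lower at an unadjusted p under 0.05, 2 lower by DESeq2; camera adjusted p = 0.00251; adjusted p = 0.547 with an estimated correlation). Of 8 thalamic genes, with Prkcd at -0.61, 2 fell adjusted over the list alone (2 lower at an unadjusted p under 0.05, 2 by DESeq2; camera adjusted p = 0.0457; adjusted p = 0.599 with an estimated correlation). Of 10 CA2 and CA3 genes, with Nectin3 at -0.48, 2 fell adjusted over the list alone (1 higher and 4 lower at an unadjusted p under 0.05, 3 lower by DESeq2; camera adjusted p = 0.0459; adjusted p = 0.433 with an estimated correlation).

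Lists of dividing and newborn cells and of chromatin regulators shifted up at E16.5 by camera. Mean log2 CPM of BAF subunits was 6.61, 6.67 and 6.71 in WT replicates 1 to 3 and 6.9, 6.8 and 6.67 in cKO. For writers and erasers it was 6.27, 6.28 and 6.3, and 6.51, 6.48 and 6.32. In both lists the rise lay mainly in cKO replicates 1 and 2, where meningeal levels were lowest (-0.71 and -0.1, against 2.39). The neuroblast list of cKO replicate 1 (6.56) lay within WT (6.41 to 6.57), while the cell division list lay above WT in each cKO library. Of 25 cell division genes 23 had a positive change, with a median of 0.25 and Mcm5 at 0.42 (SE 0.08). Of these 0 passed edgeR over all genes and 11 rose adjusted over the list alone (14 higher at an unadjusted p under 0.05, 4 by DESeq2; camera adjusted p = 9.90e-07; adjusted p = 0.433 with an estimated correlation). Of 15 genes of intermediate progenitors and neuroblasts Neurog1 rose (3 adjusted over the list alone, 5 by DESeq2; camera adjusted p = 4.87e-05; adjusted p = 0.418 with an estimated correlation). Of 27 BAF subunits 0 passed edgeR over all genes, and 5 rose and 1 fell adjusted over the list alone (9 higher and 1 lower at an unadjusted p under 0.05, 5 and 1 by DESeq2). Actl6a, the progenitor-stage subunit, was at 0.40 (SE 0.07), and camera gave adjusted p = 4.58e-05 (adjusted p = 0.46 with an estimated correlation). Of 21 writers and erasers of the profiled marks 0 passed edgeR over all genes, and 3 rose and 1 fell adjusted over the list alone (11 higher and 1 lower at an unadjusted p under 0.05, 3 higher by DESeq2). The H3K27 methyltransferase Ezh2 was at 0.51 (SE 0.09), and camera gave adjusted p = 0.000148 (adjusted p = 0.433 with an estimated correlation).

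The other 10 lists tested did not pass camera at E16.5, and 0 of their genes passed edgeR over all genes. Radial glia and neural stem cells (Slc1a3 -0.78, edgeR adjusted p = 0.0686) had 1 rising and 2 falling adjusted over the list alone, as at an unadjusted p under 0.05 and by DESeq2. The striatum (Ppp1r1b 1.80) had 1 rising adjusted over the list alone and by DESeq2, and p53 targets and apoptosis (Trp53inp1 0.37) had 1 rising and 1 falling by either count. The remaining 7 had 0 adjusted over the list alone. Of these, DESeq2 called 2 genes higher and 2 lower of axon guidance (Sema3c -1.19; 5 and 3 at an unadjusted p under 0.05) and 1 lower of cortical hem and Cajal-Retzius cells (Lhx5 -1.12; 2 lower at an unadjusted p under 0.05). DESeq2 called 0 in CA1 (Man1a -0.73), immediate early genes (Dusp1 0.24), GABAergic interneurons (Sst -0.87), erythrocytes (Hba-a2 -0.41) and mitochondrial RNAs (mt-Nd4 -0.22), where 1 gene was higher and 1 lower in each of the first pair, and 0 in the rest, at an unadjusted p under 0.05. The median and mean differed in sign for CA1 (-0.16 and 0.24), p53 targets (0.04 and -0.08), GABAergic interneurons (-0.02 and 0.02) and immediate early genes (0.03 and -0.10), and the axon guidance test pointed up with a median of -0.07 and a mean of -0.01. In total 17 of 27 lists passed camera, and 0 did by fry or with an estimated correlation, where degrees of freedom were few. Splits of the 6 libraries that mix the genotypes gave 7 to 17 lists by camera, so these camera results are weak evidence for genotype.

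Testing the difference between ages asked whether the cKO effect itself changed. In 1 fit of the 10 RNA libraries, 81 genes had a higher and 140 a lower effect at P21 than at E16.5 among 18979 tested. This fit shares its estimate of replicate spread between the ages. Dlk1 rose at P21 and had -0.81 at E16.5 (difference 3.90, SE 0.51, edgeR adjusted p = 0.0255). Angptl4, a lipase inhibitor, had 2.37 at P21 and -2.08 at E16.5 (difference 4.45, SE 0.75, edgeR adjusted p = 0.0363), and Spp1 had 1.92 and -2.26 (difference 4.18, SE 0.65, edgeR adjusted p = 0.0305). At E16.5 the mean log2 CPM of meningeal genes differed by -3.74 between genotypes, so differences between ages may hold sampled tissue as well as age. C1ql2 had -2.16 at P21 and 0.50 at E16.5 (difference -2.66, SE 0.31, edgeR adjusted p = 0.019), and the myelin connexin Gjb1 had -2.5 and 0.46 (difference -2.96, SE 0.46, edgeR adjusted p = 0.0301). Both were barely expressed at E16.5, C1ql2 at 0.655 CPM in WT and 0.925 in cKO and Gjb1 at 0.262 and 0.362. The count of 221 fell to 7 without P21 cKO replicate 2, to 9 and 14 without P21 WT replicates 1 and 2, to 101 without P21 cKO replicate 1, to 53, 23 and 60 without E16.5 WT replicates 1, 2 and 3 and to 20 without E16.5 cKO replicate 2, and was 612 without E16.5 cKO replicate 3. With the replicate block it was 1, and DESeq2 called 1179.

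Calls at both ages overlapped among lower genes. Among 15851 genes tested at both ages, 5 were lower at each age, namely Arid1a, Grp, Inka2, Thrsp and Cyp4f16, where 0.735 would be shared by independent lists (Fisher's exact test, two-sided, p = 0.00063). Arid1a is the targeted gene, and without it 4 were shared where 0.695 would be (Fisher's exact p = 0.00437). Thrsp and Cyp4f16 were named after their values were seen. At P21 Grp had a log2 change of -1.13 (SE 0.22), Inka2 of -0.68 (SE 0.11), Thrsp of -0.83 (SE 0.16) and Cyp4f16 of -1.37 (SE 0.26). Of 423 higher genes at P21 and 1 at E16.5, 0 were shared by edgeR (Fisher's exact p = 1). DESeq2 shared 100 lower genes where 35.8 would be by chance (Fisher's exact p = 2.13e-21) and 9 higher genes where 10.1 would be (Fisher's exact p = 0.872). With the replicate block edgeR called no gene at E16.5, so 0 were shared. Across genes, which are not independent replicates, the effects at the 2 ages had a Spearman rho of 0.027. Of 613 genes lower at P21, 421 lay below 0 at E16.5, and of 423 higher genes 133 lay above 0. Called genes thus leaned down at E16.5 whichever way they had changed at P21. The overlap of genes higher at P21 with genes lower at E16.5 was not tested, so the shared lower genes do not by themselves show a shared direction.

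At 3 weeks the cKO lists held more peaks than the WT lists for each mark, and the difference was greatest for H3K27me3. H3K27me3 had 4124 peaks over 2.86 Mb in WT and 15659 over 13.0 Mb in cKO, H3K27ac 13006 over 5.17 Mb and 24065 over 11.6 Mb, and H3K4me3 25145 over 21.1 Mb and 28234 over 24.5 Mb. Nearly the whole WT set was found again for H3K27me3, where 97.9% of WT peaks overlapped a cKO peak (Wilson 95% interval 97.4 to 98.3), against 91.2% (90.9 to 91.6) for H3K4me3 and 85.2% (84.5 to 85.8) for H3K27ac. Of cKO peaks 77.0% overlapped a WT peak for H3K4me3, 42.3% for H3K27ac and 13.4% for H3K27me3. Tags after duplicate removal numbered 18009991 in WT and 17399169 in cKO for H3K27me3, 19291198 and 19288471 for H3K27ac, and 18488657 and 17795796 for H3K4me3. With 1 library per genotype and mark these values compare libraries, have no replicate check, and their intervals cover counting error only.

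**Figure D3:**
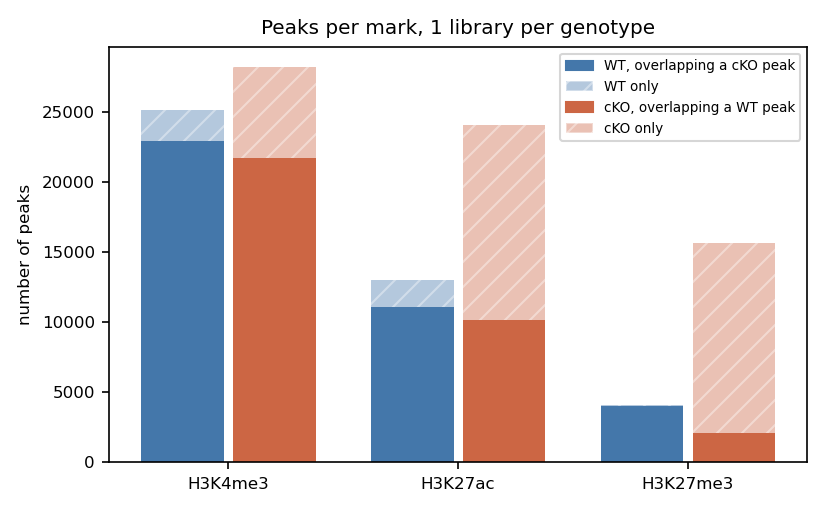
Number of peaks per mark in the WT and cKO lists, split into peaks that overlap the other list by at least 1 bp and peaks that do not (1 library per bar). Of 15659 H3K27me3 peaks in cKO 13565 had no WT overlap, and of 24065 H3K27ac peaks 13897.

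By the authors' fold enrichment, the 5 highest H3K27me3 peaks included one near Foxe3 in WT, and in cKO peaks at Dlx6 (chromosome 6, 6859087 to 6866524), at Lbx1 and at Hoxa3 and Hoxa4. All 39 Hox genes had an H3K27me3 peak within 1 kb of an end in both lists, and 0 in WT and 5 in cKO had an H3K4me3 peak there. Among radial glia and neural stem cell genes 2 of 15 had an H3K27me3 end peak in WT and 13 in cKO, among dentate granule neuron genes 1 of 13 and 8, and among oligodendrocyte lineage genes 4 of 15 and 9. Among immediate early genes 3 of 13 had one in each list, and among writers and erasers of the marks 0 of 21. H3K4me3 peaks that overlapped an H3K27me3 peak numbered 655 (2.60%) in WT and 4259 (15.1%) in cKO. The H3K27me3 list covered 2.86 Mb in WT and 13.0 Mb in cKO, which raises such overlaps by itself. Arid1a had H3K4me3 and H3K27ac peaks at its ends in both lists, with the strongest H3K4me3 peak at 133756295 to 133757434 in WT and 133756188 to 133757412 in cKO.

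H3K27me3 end peaks in cKO stood at named genes that rose and at named genes that fell. Of genes not called at P21, 2.7% had such a peak in WT and 13.7% in cKO. Twist1 and Dlk1, which rose at P21, had H3K27me3 end peaks in both lists, with the strongest Twist1 peak at chromosome 12, 33956662 to 33957947 in WT and 33956805 to 33959720 in cKO, and Hes5, Sox9 and Drd1, which also rose, had one in the cKO list and none in WT. The lower genes C1ql2, Robo3 and Tnfrsf25 likewise had H3K27me3 end peaks in cKO and none in WT, at chromosome 1, 120340103 to 120343379 for C1ql2.

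Relating peaks to RNA at P21 asked whether genes that changed gained peaks at their ends. H3K27me3 end peaks were found in WT at 7.96% of 452 higher genes, 3.08% of 649 lower genes and 2.70% of 14826 genes not called, and in cKO at 27.9%, 24.0% and 13.7%. Higher genes carried a WT H3K27me3 peak more often than genes not called (odds ratio 3.11, Fisher's exact test, two-sided, adjusted p = 7.64e-08), and both higher and lower genes carried a cKO peak more often (odds ratios 2.44 and 2.0, Fisher's exact adjusted p = 1.32e-13 and 1.92e-11). Among genes with a peak, higher genes had it in cKO alone more often than genes not called for H3K4me3 (28 of 322 marked in cKO against 318 of 12118, odds ratio 3.53, Fisher's exact p = 9.07e-08) and H3K27ac (odds ratio 1.61, p = 0.000565, Fisher's exact), and less often for H3K27me3 (odds ratio 0.612, p = 0.0215, Fisher's exact). Lower genes with an H3K27me3 peak had it in cKO alone more often (odds ratio 1.66, Fisher's exact p = 0.035), with no difference past the threshold for H3K4me3 (1.37, Fisher's exact p = 0.192) or H3K27ac (0.966, Fisher's exact p = 0.816). Over the whole gene span the H3K27me3 ratio of higher genes was 0.712 and no longer passed (Fisher's exact p = 0.0853). These ratios depend on how many genes already had a WT peak. Below, gained means a peak in the cKO list and none in the WT list, which higher enrichment in the cKO library could also give. Among genes without a WT end peak, H3K27me3 was gained at 21.6% of 416 higher genes, 21.6% of 629 lower genes and 11.3% of 14425 genes not called (odds ratio 2.17 for either group, Fisher's exact adjusted p = 1.4e-08 and 5.28e-12), with no difference between lower and higher genes past the threshold (odds ratio 0.999, Fisher's exact p = 1). In the same way H3K27ac was gained at 30.5% of higher, 27.8% of lower and 38.9% of genes not called (odds ratios 0.687 and 0.602, Fisher's exact adjusted p = 0.00459 and 1.66e-05), and H3K4me3 at 18.1%, 9.24% and 10.8% (odds ratios 1.82 and 0.839, Fisher's exact adjusted p = 0.0152 and 0.701). The direction for higher genes therefore differed between the ways of counting for H3K27me3 and H3K27ac. Genes are not independent replicates, and the first 18 tests and these 9, added after seeing the data, were each adjusted together.

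**Figure D4:**
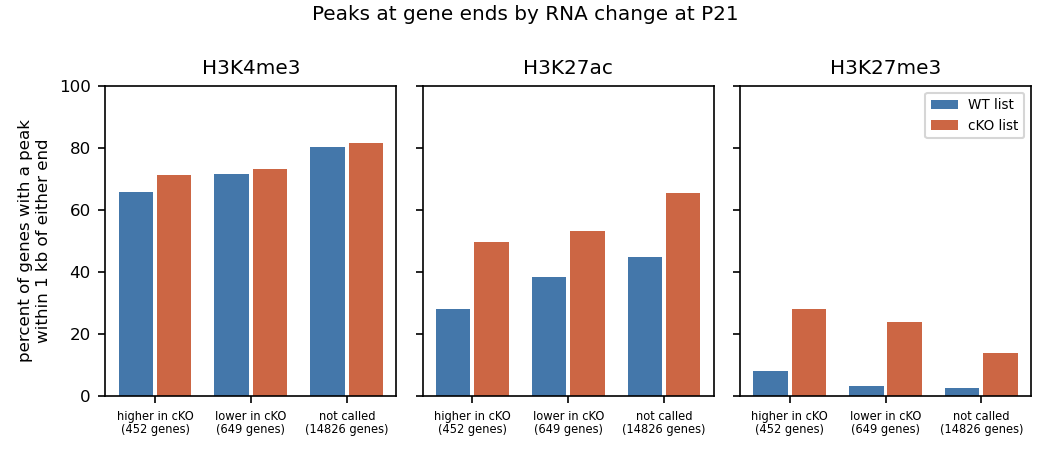
Percent of genes with a peak within 1 kb of either end in the WT and cKO lists, for genes higher (452), lower (649) or not called (14826) at P21. H3K27me3 shares rise from 7.96% to 27.9% for higher genes and from 2.70% to 13.7% for genes not called.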

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

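In this part the tests of choroid plexus and meningeal genes, the splits for counts of genes and the fits with marker covariates were chosen after the result was seen.

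The cKO effect differed between ages for 221 genes by edgeR's test of the difference itself. The named differences in log2 change, P21 minus E16.5, were 4.45 for Angptl4, 4.43 for Gdf5, 4.18 for Spp1, 3.90 for Dlk1 and 3.87 for Folh1, and -2.96 for Gjb1, -2.94 for Pimreg, -2.66 for C1ql2, -2.54 for Rlbp1 and -2.40 for Vipr1. Gdf5 had 0.0272 CPM in WT and 0.369 in cKO at P21 and Pimreg 0.46 and 0.0777, so their differences rest on few counts. Levels were also low at E16.5 for Gjb1 (0.262 CPM in WT and 0.362 in cKO), C1ql2 (0.655 and 0.925), Folh1 (1.374 and 0.1385) and Vipr1 (1.161 and 3.615). The E16.5 effects also stand beside the difference of -3.74 in mean log2 CPM of meningeal genes between genotypes. Without 1 library the count of 221 became 9 (P21 WT replicate 1), 14 (P21 WT replicate 2), 101 (P21 cKO replicate 1), 7 (P21 cKO replicate 2), 53, 23 and 60 (E16.5 WT replicates 1, 2 and 3), 20 (E16.5 cKO replicate 2) and 612 (E16.5 cKO replicate 3).

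For 14 of 28 lists camera found a difference between ages, and for 0 with an estimated correlation, where adjusted p lay between 0.321 and 0.73. The P21 effect lay above the E16.5 effect for endothelial and mural cells (camera adjusted p = 4.96e-05), extracellular matrix and cell adhesion (4.96e-05), meningeal fibroblasts (5.56e-05), CA2 and CA3 pyramidal neurons (0.00191), astrocytes (0.00291), striatum (0.00434), thalamus (0.0335) and choroid plexus and ependyma (0.0335). It lay below for writers and erasers of the marks (0.000135), BAF complex subunits (0.000152), cell division (0.00016), intermediate progenitors and neuroblasts (0.000229), immediate early genes (0.000695) and axon guidance (0.0162).

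The low choroid plexus and meningeal genes in cKO at E16.5 bear on several of these lists. Uneven carry-over of choroid plexus in dissection is consistent with the marker means, whose largest range within a genotype was 2.70 times the difference between genotypes (exact permutation p = 0.4, two-sided). For meninges this ratio was 0.843 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow), so uneven carry-over and a genotype effect cannot be told apart with levels that part the genotypes in these 6 libraries. With the choroid plexus markers as a covariate edgeR called 19 genes, 13 of them among the 21 calls, and with the meningeal markers 0, where 258 genes were higher and 475 lower at an unadjusted p under 0.05, a covariate whose mean itself differs by -3.74 between the genotypes. An effect of Arid1a loss on these tissues stays open and was not tested.

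The 6 E16.5 libraries make 10 splits into 3 and 3, too few for a share under 0.05. By edgeR the real split gave 21 genes and the highest other 35, with 19 and 35 in the lower direction and 2 and 0 in the higher direction. Camera at the preset correlation passed 17 lists in the real split and 7 to 17 in the others. Its number of lists therefore does not set the genotype split apart from other groupings of these libraries. Counting the real one, 2 splits gave as many genes, 2 as many lower, 1 as many higher and 2 as many lists. The split with 35 genes set WT replicates 1 and 2 and cKO replicate 3 against the others, the libraries with the highest choroid plexus levels (5.64, 5.13 and 4.89), which points to a structure of the samples. By DESeq2 the real split gave 1066 genes, that split 546 and the others 3 to 26.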

How the results depend on the processing

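The sex, choroid plexus and meningeal covariates, edgeR without robust fitting, the likelihood ratio test, the whole gene span, the restriction to genes without a WT end peak and the overlap without Arid1a were chosen after seeing the data. Of 143 values of the main results under alternatives 64 kept their direction and side of the threshold, or stayed within 1.5 times or their interval. For the others the cause was not tested, except where fewer genes, libraries or peaks enter by construction. Of named genes at P21, 884 of 1007 values kept direction and side of the threshold, 116 lost and 7 gained the call, and 0 reversed. At E16.5 these were 537 of 664, 91, 34 and 2, the 2 being Foxj1 (0.07) and Hba-a2 (0.23) with the meningeal covariate.

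At P21 (489 higher, 680 lower) edgeR called 921 and 1228 with no filter, 71 and 149 at an adjusted p under 0.01, 267 and 277 at 2-fold, 155 and 350 in 1 fit of all libraries, 321 higher without robust fitting and 803 higher by the likelihood ratio test. DESeq2 called 1337 genes, 1000 of them among the 1169 edgeR calls. At E16.5 (2 and 19) DESeq2 called 352 and 714, edgeR 24 and 105 with no filter, 4 higher at 1 CPM, 32 and 146 in 1 fit of all libraries, 1 and 3 with the sex covariate, and 131 and 476 by the likelihood ratio test. At an adjusted p under 0.01 edgeR called 0 and 0 (1548 and 1951 at an unadjusted p under 0.05), and with the meningeal covariate 0 and 0 (258 and 475). Lists past camera numbered 10 at P21 and 17 at E16.5, against 0 and 0 with an estimated correlation and 1 and 0 by fry. The test with an estimated correlation also has few degrees of freedom. For the difference between ages (221) DESeq2 called 1179, edgeR 358 with no filter, 4 at an adjusted p under 0.01 and 132 at 2-fold. Genes shared by both ages (5) were 109 by DESeq2, 23 with no filter and 0 at an adjusted p under 0.01.

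Leaving out 1 library gave 138 to 1244 genes higher and 293 to 1627 lower at P21 (lowest without WT replicate 2, highest without cKO replicate 1; 249 and 394 without WT replicate 1), with 6 to 11 lists, where the lone library of a genotype is assumed to vary like the others. At E16.5 it gave 0 to 4 higher and 0 to 13 lower (4 and 4 without WT replicate 2, 1 and 8 without cKO replicate 1, 1 and 5 without cKO replicate 2, and 0 without WT replicate 1 or 3, with 997 and 1335, and 1281 and 1780, at an unadjusted p under 0.05), with 13 to 17 lists, and for the difference between ages 7 (without P21 cKO replicate 2) to 612 (without E16.5 cKO replicate 3), outside 1.5 times for each library but E16.5 cKO replicate 1.

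Same-numbered libraries did not deviate together (correlation 0.02 at P21, and -0.228, -0.021 and -0.492 at E16.5, where 0 of 3 correlated best with its own number), so by this measure the libraries share a number alone. By Xist, however, same-numbered libraries also had the same sex in both genotypes at each age, so at P21 the replicate block equals sex and at E16.5 it includes sex. With the replicate block edgeR called 361 and 501 genes at P21, 0 and 0 at E16.5 (719 and 1231 at an unadjusted p under 0.05), 1 for the difference between ages (2370 unadjusted) and 0 at both ages, and camera 9 and 15 lists.

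The share of WT peaks overlapped moved from 91.2% to 85.6% for H3K4me3, 85.2% to 79.3% for H3K27ac and 97.9% to 95.8% for H3K27me3 when 50% of the WT peak had to overlap, and to 88.9%, 71.6% and 91.8% with as many top-ranked peaks in both lists. It was 87.9% for H3K27ac at −log10 q of at least 5. For lower in place of higher genes the odds ratio of a peak in cKO alone was 1.37 for H3K4me3 (Fisher's exact p = 0.192), 0.966 for H3K27ac (p = 0.816, Fisher's exact) and 1.66 for H3K27me3 (p = 0.035, Fisher's exact), the last 2 in the other direction. Over the whole gene span the H3K27me3 ratio of higher genes was 0.712 (Fisher's exact p = 0.0853). Among genes without a WT end peak the ratio of higher genes was in the other direction for H3K27ac (0.687, Fisher's exact p = 0.00204) and H3K27me3 (2.17, Fisher's exact p = 3.12e-09). This test sets genes with a peak in cKO alone against genes with a peak in neither list. The main test sets them against genes with a peak in both. Genes with a WT peak, a share that differs between the groups, thus no longer enter, and genes without any peak do. Depth limits the low genes, since at these totals 3 counts are 0.15 CPM at P21.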

Other observations

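In this part the tests of microglial and oligodendrocyte genes, of tag numbers, of genes near Arid1a and of peaks gained at genes without a WT end peak were chosen after the result was seen.

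The share of genes with end peaks varied from list to list, in examples picked after the counts were seen. Lists were not tested against each other. Of 14826 genes not called at P21, 2.7% had an H3K27me3 end peak in WT and 13.7% in cKO, and 80.2% and 81.7% an H3K4me3 one. H3K27me3 end peaks marked 11 of 17 genes of GABAergic interneurons in WT and 15 in cKO, and 11 and 12 of 14 genes of cortical hem and Cajal-Retzius cells. H3K4me3 end peaks marked 25 of 25 cell division genes and 27 of 27 BAF subunits in both lists, but 1 of 12 microglial genes in each. Peaks of H3K27ac that overlapped an H3K27me3 peak numbered 4 in WT and 1393 in cKO. Both cKO lists also covered more (13.0 against 2.86 Mb for H3K27me3, 11.6 against 5.17 Mb for H3K27ac), and lists of equal size were not compared. H3K4me3 peaks of cKO without WT overlap lay within 1 kb of a gene end in 29.1% of cases, against 68.2% of all WT peaks, and inside genes in 57.2%. Their median fold enrichment was 4.84, against 9.68 for WT peaks that overlapped a cKO peak and 5.12 for those that did not. WT peaks without cKO overlap were not placed relative to genes, so whether this contrast is particular to cKO was not tested. With 1 library per genotype none of these differences has a replicate check.

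Genes called at P21 mostly lay below 0 at E16.5, whichever way they had changed. Of 613 lower genes tested at both ages 421 were also below 0 at E16.5, and of 423 higher genes 133 were above 0. In all 53.5% of the called genes had the same sign at both ages, against 52.1% of all genes tested at both. Bcan, which fell at E16.5, had a log2 change of 0.19 (SE 0.16) at P21, and Aldoc had -0.37 (SE 0.11, edgeR adjusted p = 0.0802). Ugt1a6b, without counts in WT at P21, had 8.94, 5.34 and 0.41 CPM in the E16.5 WT libraries and 0, 0 and 3.998 in cKO, where Ttr had 4566, 3070 and 16.3 and 0.953, 27.1 and 2336.

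Low oligodendrocyte and microglial RNA in cKO at P21 may come from fewer cells, from less RNA per cell or from a difference in dissected tissue. Striatal markers differed between the same libraries (mean log2 CPM 2.06 and 2.26 in WT, 3.09 and 3.7 in cKO), and a difference in dissected tissue was not tested for the glial genes. If fewer microglia were the whole cause, the markers would fall alike, but 8 of 12 lay more than 2 standard errors from their median of -0.51, from P2ry12 at -2.27 to Cd68 at 0.66. Fewer cells of the whole oligodendrocyte lineage is likewise argued against, since 11 of 15 markers lay that far from their median of -0.87, from Mog at -1.84 to Pdgfra at 0.16. A change of microglial state, and fewer mature oligodendrocytes with progenitors kept, stay open as hypotheses and were not tested. These standard errors rest on 2 libraries per genotype.

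The larger H3K27me3 and H3K27ac lists in cKO may reflect gained marks or a more efficient immunoprecipitation. Deeper sequencing is argued against, since the cKO libraries had 0.966 and 1.0 times the tags of WT. Of the strongest cKO peaks by q-value, as many as the WT list holds, 43.7% overlapped a WT peak for H3K27me3 and 63.0% for H3K27ac, in a test of whether the same regions were seen with higher enrichment. For H3K27me3 the first value met the bound of under 50% set beforehand against that explanation, but the bound was wrong, because long cKO peaks join several WT peaks (2094 cover 4037) and no more than 50.8% could overlap (78.2% for H3K27ac), so regions gained and regions better enriched cannot be told apart here. Among peaks that overlapped the other list, the median fold enrichment was 4.99 in WT and 9.37 in cKO for H3K27me3. It was 5.43 and 7.61 for H3K27ac, and 9.68 and 9.85 for H3K4me3. Peaks in cKO alone had 4.81, 5.29 and 4.84. The median of shared peaks was thus higher in the cKO list for H3K27me3 and H3K27ac. These medians cover 4037 WT and 2094 cKO peaks for H3K27me3, and 11075 and 10168 for H3K27ac, and regions were not matched. A cKO peak that joins several WT peaks has 1 value, which may by itself raise the cKO median. A more efficient immunoprecipitation would also give higher medians, and so would more mark at these regions. Among genes with an end peak, it was in cKO alone more often at lower genes than at genes not called (odds ratio 1.66, Fisher's exact p = 0.035, adjusted p = 0.042), which met the bound set beforehand in favour of H3K27me3 gained at genes with less RNA, but that bound asked for no comparison with higher genes, and in the comparison added afterwards, among genes without a WT end peak, the gain was 21.6% at lower and at higher genes, so the data do not single out genes with less RNA.

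Genes within 10 Mb of Arid1a were called at P21 in 30 of 281 cases (10.7%) against 6.83% elsewhere (odds ratio 1.63, Fisher's exact p = 0.0169), but 7.99% of 1301 windows of that size had as high a share, so a stretch of other-strain DNA around the targeted allele remains undecided. Matn1, Hdac1 and Ephb2, named above at P21, lie within this window. Whether their changes follow from the loss of Arid1a or from such DNA was not tested.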
